A study of Sus scrofa with 12 samples.

How the data were processed

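Small RNA libraries had been prepared with a NEBNext kit from vesicle RNA of 4 minipig donors, 3 culture methods each, per the labels' protocols. Reads were aligned with Bowtie, per the submitters' processing notes. The aligner's version, the genome build, the miRNA annotation and the counting step are not given in the sources used here. The deposited values are a signal on a linear scale, named a normalized read count per mature miRNA in the file header. Within each library every value was a whole multiple of 1 step, within 0.001 of a read, and the steps were proportional to median-of-ratios size factors recomputed from the same 252 rows. The values thus equal reads divided by 1 factor per library, and reads per library were recovered from the steps. No value above 0 stood for fewer than 2 reads, and the values of 0, 1 to 28 in each library, were analysed as listed. All 12 columns were matched to samples by library number.

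The design fixed before the data were examined foresaw a count test, or limma on log2 values if the table held normalized values, which it did. Each comparison was fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance (trend), on log2(value + 1) for miRNAs at 1 or more in at least 4 of 12 libraries, which all 252 were. All 12 libraries entered 1 fit with culture method as the only factor, and p-values were adjusted by the Benjamini-Hochberg method. Fold changes are on the log2(value + 1) scale, which understates the change of miRNAs that are low in every library and can overstate it where single libraries of a group are listed at 0, and no fold is given against a group listed at 0.

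Same-numbered samples came from the same donor, so donor numbers pair the libraries, and a fit with donor as a block was foreseen beside the one without. Deviations of same-donor libraries from their group means correlated at 0.02 to 0.67. Replicates came from separate animals, and no replicate pair agreed within sampling noise.

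Lists of miRNAs (23, from families, clusters, stromal function and markers of other cell types and serum) were fixed before the data were examined. The 19 with 4 or more measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The named miRNAs followed a fixed rule: per comparison, of the calls that moved the same way in all 4 donors, the 10 largest rises and 10 largest falls, the 10 most abundant miRNAs, and up to 4 members of each list with the smallest p.

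Whole profiles were compared by PERMANOVA on Euclidean distances with exact enumeration of groupings. Detection was counted after thinning to 264407 reads (mean of 20 draws). Group means of single values were compared by exact two-sided permutation of 4 against 4 libraries, which cannot give a p below 0.0286. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 was used. The alternatives were the donor block, library totals, other pseudocounts and filters, fits of 2 groups, lists left out and each library left out. Limma-voom on recovered reads, an adjusted p of 0.1, the wider set of lists left out list tests without the shallowest library, the estimated correlation under it and under the donor block, detection at 2 or more reads, and simulated and split overlaps were added after seeing the data.

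The fit was tested on counts simulated for perfusion against plate over 252 miRNAs with 50 changed, 20 times. It recovered 28.2% of 2-fold, 74.1% of 4-fold and 89.1% of 8-fold changes, with 4.67% of calls false and 0.15 calls on average with no change. The counts were drawn independently for each miRNA and library, without donor effects, and miRNAs with low means were left unchanged. Real libraries of the same donor deviate together, so these rates may not hold for the data. miR-129a-5p and miR-129b, miR-199a-3p and miR-199b-3p, and miR-218-5p and miR-218b kept a nearly fixed ratio in all libraries, and miR-9, miR-9-1 and miR-9-2, which count as 3 of the 252, held the same reads. Such rows share reads, so each is uncertain as a separate miRNA. The let-7, miR-23 and miR-27 members are also near-identical, and their reads could be split between them.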

Results

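The series measured microRNAs (miRNAs, short RNAs that repress target messages) carried by extracellular vesicles, the membrane particles that cells release. The vesicles were pelleted by ultracentrifugation from medium conditioned by bone marrow mesenchymal stromal cells of juvenile minipigs. Cells of 4 donors were grown in each of 3 ways, which gave 12 libraries with 1 library per donor and culture method. The 3 groups were flat tissue culture plates, a perfusion bioreactor in which medium circulated over a scaffold at 4 mL/min, and microcarriers in a stirred spinner flask. The labels give 10% fetal bovine serum for the plate and microcarrier medium and no serum content for the perfusion medium. The table lists 252 mature pig miRNAs as normalized read counts. The total reads per library, recovered from the steps between values, ran from 264407 (plate, donor 2) to 3253003 (plate, donor 4). Perfusion libraries held 671012 to 1614726 reads and microcarrier libraries 607776 to 2244584.

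A few miRNAs made up most of every profile. miR-21-5p, a miRNA abundant in stromal cells, held 25.7% ± 4.56 (SD, n = 12) of the normalized counts. The next highest means over the 12 libraries were those of let-7i-5p (7.32% ± 0.874), miR-27b-3p (6.94% ± 3.78), miR-148a-3p (6.33% ± 1.54) and miR-143-3p (5.79% ± 2.03). Their order differed by culture: the second highest mean share was that of miR-148a-3p on plates (7.29%), miR-143-3p in perfusion (7.49%, with let-7i-5p at 7.47%) and miR-27b-3p on microcarriers (9.63%). The other 5 of the 10 most abundant were let-7f-5p, miR-199a-3p, miR-100, let-7a and miR-26a, and the 10 together held 73.1%. The share held by the 10 leading miRNAs of each library was 73.2% ± 1.76 on plates, 74.3% ± 1.07 in perfusion and 73.5% ± 2.00 on microcarriers (SD, n = 4 each). None of the 3 differences passed an exact permutation test (two-sided, smallest adjusted p = 0.771). After every library was thinned to 264407 reads, 236.5 ± 8.43 miRNAs were detected on plates, 233.1 ± 1.85 in perfusion and 239.3 ± 4.30 on microcarriers (SD, n = 4 each). No difference in these numbers passed the exact permutation test (smallest adjusted p = 0.257), and none in log2 library totals did (smallest adjusted p = 0.886). Plate donor 2, the smallest library, was not thinned and lists no single reads, while thinned libraries can hold them. At 2 or more reads after thinning, perfusion minus plate was -7.01 miRNAs (219.5 to 222.85 in perfusion, 224 to 233.5 on plates). Its exact permutation p was 0.0286, the smallest possible, and 0.0857 after adjustment over 3 comparisons. A pair alone at that floor cannot pass whatever its difference, so the test cannot decide.

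The first question was how far the culture method set the whole profile. Culture method accounted for 50.01% of the squared distance between libraries over the 252 miRNAs, and no other of the 5775 groupings gave as much (exact permutation p = 0.000173, the smallest these groupings can give). Those groupings ignore the pairing by donor. Permuted within donors, culture gave an exact permutation p of 0.00463 over 216 arrangements. The first principal component held 42.1% of the variance and separated the perfusion libraries from the rest. By pairs of groups, culture accounted for 27.2% of the squared distance among plate and microcarrier libraries, 45.3% among plate and perfusion libraries and 53.8% among perfusion and microcarrier libraries. Each pair gave an exact permutation p of 0.0286, the smallest that 35 splits allow. These splits ignore the pairing by donor, and the 8 that part all donor pairs are too few for a p under 0.05. Donor accounted for 24.6%. With donor labels permuted over all libraries it did not pass (exact permutation p = 0.596). Each donor has 1 library per culture, while such free groupings can gather libraries of the same culture. They averaged 27.3%, so that test cannot decide on donor. Permuted within culture groups, where arrangements averaged 16.7%, donor passed (exact permutation p = 0.00174, the smallest of 576 arrangements).

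**Figure D1:**
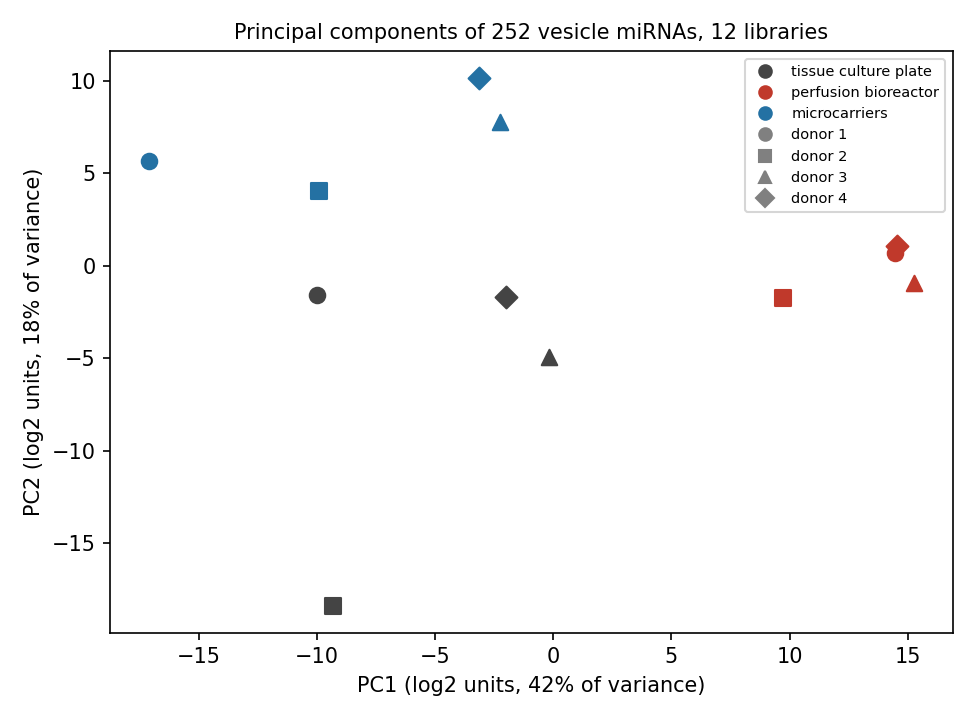
Principal components 1 and 2 of the log2 values of 252 miRNAs, in log2 units, with 1 point per library, colour for culture method and marker shape for donor. The 4 perfusion libraries lie apart on the first component, which holds 42.1% of the variance.

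The comparison of perfusion with plates asked how flow over a scaffold changed vesicle miRNAs against standard culture. Vesicles from the perfusion bioreactor carried less of 6 of the 9 measured markers of blood cells, of the 1 endothelial marker and of 1 of 3 liver and gut markers. The erythroid miR-144 fell by 4.45 ± 0.72 on the log2 scale (SE, 4 libraries per group), miR-486 fell by 4.34 ± 0.75, and the blood-cell miRNAs miR-142-5p and miR-142-3p fell by 4.31 ± 0.69 and 3.67 ± 0.81. With a pseudocount of 10 the falls of miR-144 and miR-142-3p were 2.23 and 2.18. The liver miRNA miR-122-5p fell from 550.1 ± 478 to 21.4 ± 14.0 normalized counts (SD, n = 4), the endothelial miR-126-3p from 1234 ± 738 to 144.1 ± 29.1, and the erythroid miR-451 from 972.9 ± 711 to 145.6 ± 121. The myeloid miR-223 stood at 32.7 ± 26.1 on plates and was listed at 0 in all 4 perfusion libraries. Among called miRNAs found on plates, the highest fitted rises were those of miR-454 (log2 fold change 3.67 ± 0.79), miR-331-3p (3.37 ± 0.94), miR-129a-3p (2.93 ± 0.72), miR-132 (2.26 ± 0.54) and miR-365-3p (2.24 ± 0.47). The other arm of miR-365, miR-365-5p, was lower on average in perfusion than on plates. miR-454 and miR-331-3p were listed at 0 in plate replicate 2, the shallowest library, and without it both rises were smaller, that of miR-331-3p at 2.22 below that of miR-129a-3p at 2.40.

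In all, 52 of 252 miRNAs passed an adjusted p of 0.05 in limma, 26 higher and 26 lower, and each of the 52 changed the same way in all 4 donors. miR-500-5p (1.90 ± 0.35), miR-18a (1.84 ± 0.51), miR-7-5p (1.79 ± 0.45) and miR-7134-5p (1.76 ± 0.42) completed the largest measured rises among the calls. miR-7-5p was the most abundant of these, at 14487 ± 9357 against 3707 ± 1450 normalized counts. miR-10390 was listed at 0 in all 4 plate libraries and above 0 in all 4 perfusion libraries. It stood at 231 reads in perfusion donor 1 but only at 8, 2 and 4 reads in donors 2, 3 and 4, near the lowest reads listed. miR-194a-5p (-3.17 ± 0.85) and miR-126-5p (-2.67 ± 0.68), at -1.27 and -1.33 with a pseudocount of 10, completed the largest falls among the calls.

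By list, 6 of the 9 measured markers of blood cells were lower and 1, miR-155-5p, was higher (1.74 ± 0.39). Their median log2 fold change was -2.95, a value that does not depend on the level assigned to miR-223. This was the one list of 19 tested to pass camera (adjusted p = 0.0120), and it did not with an estimated correlation (adjusted p = 0.842). Of the 8 serum-borne miRNAs, 5 were lower and 1, miR-92a, was higher (camera adjusted p = 0.232); miR-144, miR-451 and miR-486 belong to both lists. Within the miR-17-92 cluster and its paralogues, a family linked to proliferation, 3 of 9 were higher, namely miR-18a, miR-20b (1.35 ± 0.44) and miR-92a (0.87 ± 0.26), with no list call (adjusted p = 0.232). In the let-7 family, known for roles in differentiation, 2 of 8 were lower: let-7c (-1.80 ± 0.28) and let-7a (-0.99 ± 0.28). Among 15 hypoxia-induced miRNAs, miR-210 (1.50 ± 0.39) and miR-23a (0.90 ± 0.30) were higher and miR-27a (-1.03 ± 0.29) was lower (adjusted p = 0.939). Of 10 cartilage-related miRNAs, miR-140-3p (-1.20 ± 0.38) and miR-320 (-0.91 ± 0.29) were lower (camera adjusted p = 0.813). The other arm of miR-140, miR-140-5p, did not fall. Of 3 muscle markers, miR-499-5p (-1.14 ± 0.31) and miR-1 (-1.71 ± 0.56) were lower, while miR-133a-3p was not called and was higher on average. Of 29 mesenchymal stromal miRNAs, 1 was higher and 1 lower (adjusted p = 0.939), and of 13 flow-responsive miRNAs 2 were higher and 1 lower (adjusted p = 0.939). Of 12 immune-regulating miRNAs 2 were higher, miR-132 and miR-155-5p, and 3 lower (adjusted p = 0.813). In the miR-29 and miR-30 families miR-30e-5p was the 1 lower of 8 (-1.35 ± 0.29; adjusted p = 0.939). No member of the miR-15/16 family (7), the miR-10/99/100 family (5), the p53-induced list (6) or the epithelial markers (3) was called. Among 5 neural markers, 10 osteogenesis-promoting and 10 osteogenesis-restraining miRNAs 1 each was higher, and the smallest adjusted p of those 3 lists was 0.684. Adjusted over the list alone, the blood-cell markers again gave 6 lower and 1 higher, the serum-borne list 5 and 1, and the hypoxia list 1 lower and 1 higher.

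The count of 52 fell to 29 without perfusion replicate 1 and to 30 without perfusion replicate 3. Among the named calls, those of miR-331-3p, miR-18a, miR-194a-5p, let-7a, miR-210, miR-23a, miR-27a, miR-92a, miR-20b, miR-320, miR-140-3p, miR-499-5p and miR-1 ended when some single library was left out, and so did those of miR-331-3p, miR-23a and miR-1 with a pseudocount of 0.1, miR-194a-5p and miR-10390 with one of 10, miR-194a-5p and miR-20b in limma-voom, miR-20b and miR-23a without the blood-cell, endothelial, liver and serum lists (miR-23a without the serum list too), miR-320 under library totals, and miR-92a and miR-140-3p in fits of only 2 groups.

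**Figure D2:**
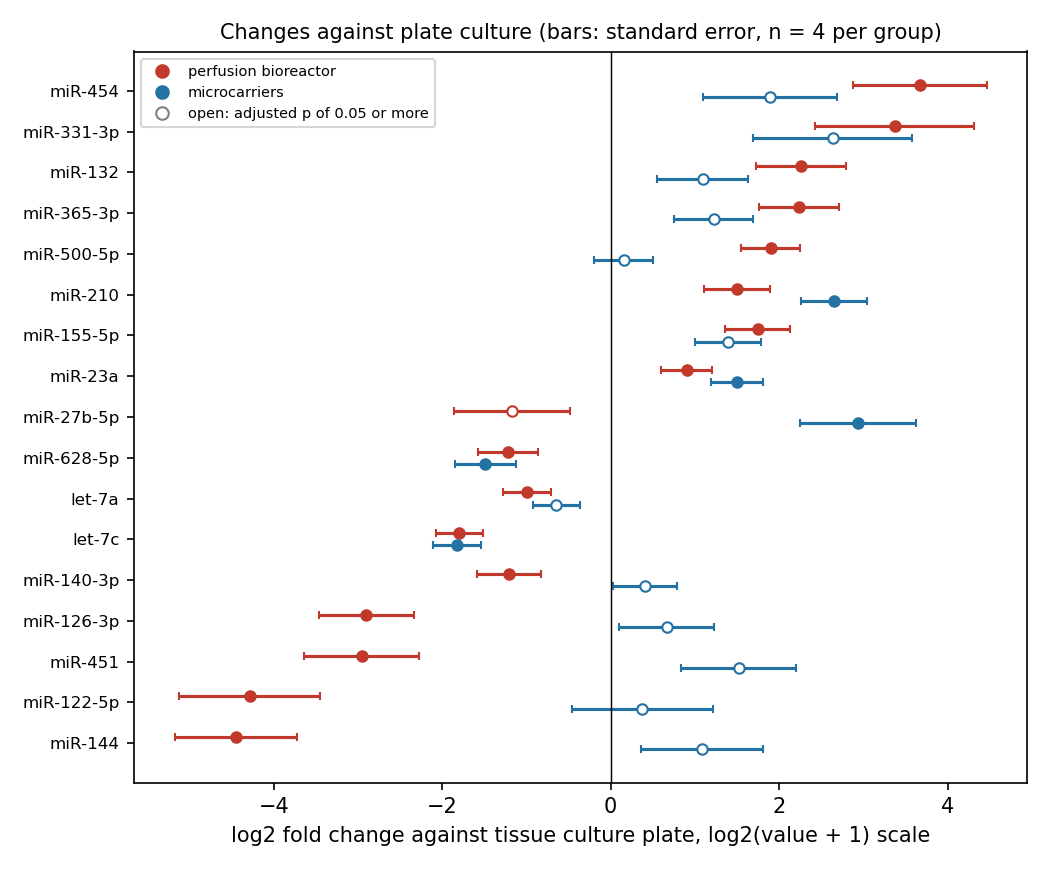
Log2 fold changes against tissue culture plates on the log2(value + 1) scale for 17 named miRNAs in perfusion and on microcarriers, with standard errors (4 libraries per group) and open symbols where the adjusted p was 0.05 or more. miR-210 and let-7c changed in both cultures, while miR-144, miR-451, miR-122-5p and miR-126-3p fell in perfusion and were not called on microcarriers.

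The comparison of microcarriers with plates asked the same of a stirred culture on beads. The hypoxia-induced miR-210 rose from 145.8 ± 46.1 to 967.7 ± 428 normalized counts (SD, n = 4; log2 fold change 2.65 ± 0.39). miR-27b-5p rose by 2.93 ± 0.69 and miR-23a by 1.50 ± 0.30. The other and far more abundant arm, miR-27b-3p, was not called, at 79130 ± 44976 normalized counts on plates and 123049 ± 46100 on microcarriers. let-7c fell by 1.83 ± 0.28 and miR-628-5p fell by 1.49 ± 0.36. miR-10390, listed at 0 in all 4 plate libraries, reached 42.6 ± 21.5 on microcarriers.

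miR-27b-3p aside, these 6 miRNAs, 4 higher and 2 lower, were the calls at an adjusted p of 0.05 in limma. Each of the 6 moved in the same direction in all 4 donors, while 51 miRNAs had an unadjusted p under 0.05. With donor as a block the count rose to 23, 13 higher and 10 lower, and included all 6. Under that block miR-155-5p (1.39), miR-23b (1.61), miR-222 (1.62) and miR-106a (1.33) were higher. The smooth muscle and stromal pair miR-143-3p (-0.74) and miR-145-5p (-1.23), miR-196b-5p (-1.16), miR-133a-3p (-1.17) and miR-218-5p (-2.32) were lower.

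No list passed camera. The miR-23/27/24 clusters had 1 of 5 members higher (adjusted p = 0.183). The markers of blood cells had none of 9 called, with a median log2 fold change of 1.10 (adjusted p = 0.173), and included miR-451 (1.52 ± 0.68), miR-150 (1.43 ± 0.80) and miR-144 (1.09 ± 0.72). Without plate replicate 2 both of these lists passed (adjusted p = 0.0284 and 0.0464), and neither did there with an estimated correlation (adjusted p = 0.597 for both). The liver miRNA miR-122-5p differed by 0.38 ± 0.84, less than its error. Among 13 angiogenesis-promoting miRNAs 2 were higher, miR-210 and miR-23a (adjusted p = 0.235), and 3 were adjusted over the list alone. Adjusted over the list alone, 3 hypoxia-induced miRNAs, 2 of the miR-23/27/24 clusters and 1 marker of blood cells were higher, and all 3 muscle markers were lower. The count of 6 became 12 without plate replicate 1, and 3 without plate replicate 3 or without plate replicate 4. Of the 35 splits of the 8 libraries the true one and 1 other called 6 or more, and only the calls of miR-10390, miR-210 and let-7c held with any single library left out; miR-10390 was lost with a pseudocount of 10, miR-23a, miR-27b-5p and miR-628-5p in a fit of only 2 groups, and the last 2 also with a pseudocount of 0.1.

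The comparison of perfusion with microcarriers set both dynamic cultures side by side. Here too 6 of 9 markers of blood cells, the endothelial marker and 2 of 3 liver and gut markers were lower in perfusion. miR-144 fell by 5.54 ± 0.72 on the log2 scale (3.17 with a pseudocount of 10), miR-486 fell by 5.43 ± 0.75, miR-142-5p fell by 5.28 ± 0.69, miR-122-5p fell by 4.66 ± 0.84 and miR-451 fell by 4.48 ± 0.68 (SE, 4 libraries per group). miR-223 stood at 86.0 ± 90.2 on microcarriers and at 0 in all 4 perfusion libraries. miR-27b-5p fell by 4.10 ± 0.69. Its more abundant other arm, miR-27b-3p, was not called, at 54270 ± 29981 against 123049 ± 46100 normalized counts (SD, n = 4). miR-224 fell by 4.35 ± 0.95 (1.88 with a pseudocount of 10). In the other direction, miR-133a-3p (1.87 ± 0.37), miR-500-5p (1.75 ± 0.35), miR-145-5p (1.59 ± 0.41), miR-149 (1.31 ± 0.26) and miR-503 (1.24 ± 0.32) were higher in perfusion.

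In all, 39 miRNAs passed, 14 higher and 25 lower in perfusion, all in the same direction in 4 of 4 donors. Donor as a block gave 59, 25 higher and 34 lower, with the 39 included. Scaled to library totals, 17 were higher and 20 lower, and the median log2 fold change of all miRNAs moved from -0.07 to 0.08. Among the calls, the remaining largest rises were miR-2411 (2.86 ± 0.91, and 1.51 with a pseudocount of 10), miR-7134-5p (1.62 ± 0.42), miR-7-5p (1.61 ± 0.45), miR-7857-3p (1.36 ± 0.38) and miR-769-3p (1.26 ± 0.37). The remaining largest falls were miR-142-3p (-4.36 ± 0.81, over 1.5 times smaller with a pseudocount of 10) and miR-150 (-4.00 ± 0.80).

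Of 9 markers of blood cells 6 were lower, with a median log2 fold change of -4.48 (camera adjusted p = 4.67e-05). The call was lost with an estimated correlation (adjusted p = 0.466). Adjusted over the list alone, 7 were lower. Of 8 serum-borne miRNAs 4 were lower and 1 higher (adjusted p = 0.0852), and 5 and 1 adjusted over the list alone. miR-122-5p stood at 1088 and 817.8 normalized counts in plate donors 1 and 2 against 140.7 and 154.3 in donors 3 and 4, and at 1911 and 802.2 against 178.0 and 201.2 on microcarriers. The endothelial miR-126-3p fell by 3.56 ± 0.56, and miR-122-5p and miR-192 (-2.93 ± 0.70) were the lower ones of 3 liver and gut markers. Among 29 mesenchymal stromal miRNAs 4 were higher and 1 lower (adjusted p = 0.499), and miR-143-3p was among those higher (0.94 ± 0.25). In the miR-23/27/24 clusters 1 of 5 was lower, miR-27a (-1.36 ± 0.29), with no list call (adjusted p = 0.0852) except with donor as a block (adjusted p = 0.0288), and none there with an estimated correlation (adjusted p = 0.485). Of 8 members of the imprinted DLK1-DIO3 cluster 2 were lower: miR-493-3p (-3.35 ± 1.00) and miR-432-5p (-2.80 ± 0.80), at -2.02 and -1.54 with a pseudocount of 10, and the list had an adjusted p of 0.200. miR-140-3p, a cartilage miRNA, fell by 1.61 ± 0.38, while its other arm, miR-140-5p, fell far less. miR-210 was lower by 1.15 ± 0.39 without passing (adjusted p = 0.0645), and passed with donor as a block.

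The count of 39 was 24 without perfusion replicate 1 (4 higher and 20 lower), 29 without replicate 2 (8 and 21), 25 without replicate 3 (7 and 18) and 22 without replicate 4 (5 and 17). It was 25 when the blood-cell, endothelial, liver and serum lists were left out, and the calls of miR-2411, miR-7134-5p, miR-7-5p, miR-145-5p, miR-7857-3p, miR-769-3p, miR-503, miR-143-3p, miR-432-5p and miR-493-3p ended when some single library was left out, those of miR-432-5p and miR-493-3p also in limma-voom and with a pseudocount of 10, miR-493-3p and miR-2411 with one of 0.1, miR-493-3p in a fit of only 2 groups, and miR-2411 with a filter at 10 or without the serum list or the wider set of lists.

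**Figure D3:**
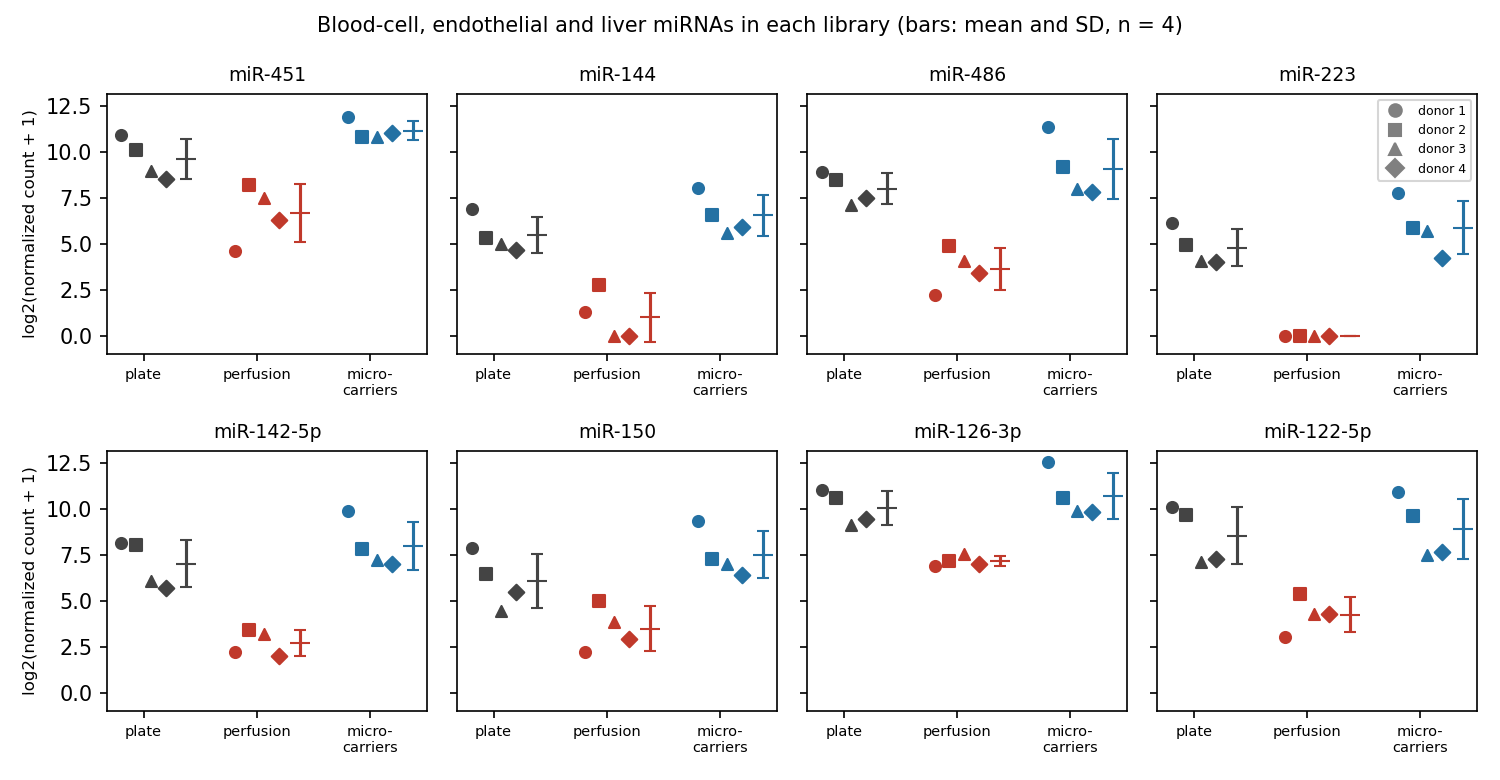
Values of 8 blood-cell, endothelial and liver miRNAs in each library as log2(normalized count + 1), by culture group, with marker shape for donor and bars for the mean and SD (n = 4). Perfusion libraries are lowest for all 8 on average, and miR-223 is listed at 0 in all 4 of them.

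Both dynamic cultures were compared with the same 4 plate libraries. Of the calls, miR-10390, miR-210 and miR-23a were higher in both and let-7c and miR-628-5p lower in both. That is 3 and 2 shared, where independent lists would share 0.413 and 0.206. In perfusion, miR-10390 stood only at 8, 2 and 4 reads in donors 2, 3 and 4. Unchanged groups simulated against shared plates shared 0.03 and 0.01 on average (at most 3 and 1 in 100 draws). Groups simulated without effects hold no real calls to share, so here and below they are no baseline for these overlaps. With the plate libraries split 2 and 2, a mean of 0.50 and 1 were shared over 6 splits, where independent lists of the split fits would share 0.180 and 0.119. The 2 comparisons of perfusion used the same 4 perfusion libraries and shared 5 higher and 17 lower miRNAs, where independent lists would share 1.44 and 2.58 and simulated unchanged groups shared 0.24 and 0.10 on average (at most 21 and 9 in 100 draws). With the perfusion libraries split 2 and 2 the comparisons shared 1.33 higher and 6.83 lower on average, 0 to 2 and 3 to 9. Independent lists of the split fits would share 0.116 and 0.519. Part of the overlaps may come from the shared libraries. Split groups of 2 also call fewer miRNAs, so the smaller overlaps cannot show how large that part is. Across miRNAs, the log2 fold changes of the 2 cultures against plates correlated at 0.23, against 0.47 on average (95% range -0.32 to 0.89) when unchanged groups were simulated against shared plate libraries. The covariance was 0.282 beside a simulated 0.173 (-0.069 to 0.594), so both lay within the range without any effect. With the plate libraries split 2 and 2 the correlation was 0.05 on average over 6 splits, and the covariance 0.0620. miRNAs are not independent replicates, so no p is given.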

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

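The tests of miR-210, of let-7c and of blood cells as a source were chosen after the results were seen. The sample flags came from Dixon's ratio above its 95% critical value in groups of 4 and numbered 13 of 169, where chance gives about 1 in 20 (8.45).

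miR-126-5p was high in donor 1 on plates (ratio 0.833, log2 value 5.96 against 3.98 to 4.31) and on microcarriers (0.921, 7.14 against 5.46 to 5.59). miR-365-3p was high in donor 1 on plates (0.855) and in perfusion (0.831). miR-210 was low in plate replicate 1 (0.885, 6.30 against 7.35 to 7.49). miR-769-3p was high in plate replicate 1 (0.854) and low in perfusion replicate 2 (0.835). miR-18a was high in perfusion replicate 3 (0.878), and miR-27a was low in microcarrier replicate 3 (0.842). Zeros set the remaining ones: miR-224 (0.904) and miR-454 (0.910) were listed at 0 in plate replicate 2, the shallowest library, miR-2411 (0.947) was listed at 0 in microcarrier replicate 4, and miR-224 (1) was above 0 in perfusion replicate 3 alone.

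The counts of miRNAs that differ were set against the 35 splits of the 8 libraries of each comparison. For perfusion against plate, only the real split gave 52 (1 of 35, the smallest share possible), and the highest other gave 0. For perfusion against microcarriers only the real split gave 39 (1 of 35), and the highest other gave 1. For microcarriers against plate 2 of 35 splits gave 6 or more. The other of these 2, with 10 calls, put donors 1 and 2 of both cultures together, which points to a structure by donor. The 35 splits ignore the pairing by donor, so their shares cannot exclude chance in any of the 3 comparisons. Among the 8 splits that part all 4 donor pairs the highest other was 0, 0 and 1 in this order, and 8 splits are too few for a share under 0.05. The donor-blocked counts were 64, 59 and 23.

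Of 9 markers of blood cells 6 were lower in perfusion than on plates, as was the liver miRNA miR-122-5p, while miR-155-5p was higher. Thinning all libraries to 1 total left the median log2 fold change of miR-122-5p and 7 blood-cell miRNAs chosen after the results were seen (miR-142-3p and the 6) at -4.44 (-4.30 before), which argues against depth. Serum in the medium may be 1 shared source. miR-122-5p and the mean of those 7 deviated the same way in 7 of 8 plate and microcarrier libraries. However, donors 1 and 2 lay above donors 3 and 4 in both cultures. The planned correlation was therefore void, and the 7 of 8 restates the same split by donor, so neither can decide on serum. Blood cells of the marrow as the only source would leave miR-122-5p, a liver miRNA, largely unmoved, yet its log2 fold change was -4.29, and 1 miRNA does not exclude blood cells for the other markers. The labels give 10% fetal bovine serum for plates and microcarriers and do not state the serum content in perfusion, so a difference in serum would follow the same groups, and these and a change in the cells cannot be told apart.

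miR-210 was higher in both dynamic cultures than on plates. Scaling to library totals left log2 fold changes of 1.57 and 2.58, which argues against the authors' scaling. A hypoxia response could raise it, but the 14 other hypoxia-induced miRNAs went both ways, and the camera test of limma gave them 0.577 in perfusion and 0.388 on microcarriers as p-values, which cannot decide. Flow, stirring and oxygen supply cannot be told apart in this design.

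let-7c was lower in both dynamic cultures. If let-7a reads counted as let-7c were its whole signal, their ratio would stay fixed, but the log2 ratio of let-7c to let-7a differed by -0.80 in perfusion and -1.18 on microcarriers (exact permutation p = 0.0286 each, lower in 4 of 4 donors). That argues against such reads as the whole cause. A change in the cells or in what they load into vesicles remains open and was not tested.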

How the results depend on the processing

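Limma-voom, the adjusted p of 0.1, the wider lists left out, list tests without plate replicate 2, the estimated correlation under that setting and under the block, detection at 2 or more reads, the simulated and split overlaps, and the left-out libraries for detection, shares, totals and donor separation were chosen after seeing the data. No call of the fit without a block was lost with donor as a block, and no call changed sign under any alternative. For perfusion against plate (52), the block gave 64 and single libraries left out gave 29 to 55. For microcarriers against plate (6), the block gave 23, a fit of only 2 groups gave 3, an adjusted p of 0.1 gave 10, and left-out libraries gave 3 to 12. For perfusion against microcarriers (39), the block gave 59, the blood, endothelium, liver and serum lists left out gave 25, and left-out libraries gave 22 to 49. Of the 39, 10 belong to the lists left out, and left-out libraries leave fewer samples; otherwise the cause was not tested. Of 34, 6 and 27 named calls, 24, 2 and 24 held under every alternative that kept all libraries and gave them a value (members of a left-out list have none there). Lists that passed numbered 1, 0 and 1. An estimated correlation gave 0 in all comparisons, also with the block or without plate replicate 2, fry gave 2, 1 and 6, the block gave 2 for perfusion against microcarriers, and leaving out plate replicate 2 gave 2 for microcarriers against plate. Culture separation was 47.5% to 53.9% with 1 library left out and 43.5% without the lists. Donor separation, 24.6%, passed with permutation within cultures. Free permutation, under which it did not pass, cannot test donor beside the culture differences. Detected miRNAs in perfusion minus plate (-3.35) were 0.50 without thinning, -7 at a value of 10, -7.01 at 2 or more reads and -7.51 to -1.46 with 1 library left out. Microcarriers minus plate (2.78) were 5.50, 3.75, 0.19 and -1.38 to 4.81, and perfusion minus microcarriers (-6.13) -5, -10.75, -7.20 and -8.16 to -4.84. The top 3 share differed by 4.73, 6.65 and -1.92 points and the top 1 share by 5.94, 5.85 and 0.10, against 1.13, 0.32 and 0.81 for the top 10. No adjusted p among these was under 0.0857. That is the least a pair alone at the smallest exact permutation p, 0.0286, can get. The top 1 and top 3 shares of perfusion against plate stood at that floor. So did detection at a value of 10 in perfusion against microcarriers, and these tests cannot exclude a difference. With 1 library left out the top 10 share ranged from 0.27 to 1.53 for perfusion minus plate, -0.53 to 1.23 for microcarriers minus plate and -0.10 to 1.51 for perfusion minus microcarriers, log2 totals from -0.95 to 0.26 for perfusion minus plate -0.50 to 0.71 for microcarriers minus plate and -0.87 to -0.24 for perfusion minus microcarriers (-0.45), and miR-122-5p on microcarriers from -0.28 to 0.89. Count tests were left out, as the design foresaw for a table of normalized values, and the recovered reads were used for limma-voom and thinning. Median-ratio scaling was not run as an alternative because the values already carry it. Sign flips of 4 donor differences cannot give a p below 0.125. Depth limits miRNAs near 0 in plate replicate 2.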

Other observations

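The test of neighbouring genes was chosen before its result was seen, but miRNAs with several gene copies were removed from it after a first version had been seen. miR-452 was named after its values were seen.

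miRNAs whose genes lie side by side moved together in several places, but not in all. In perfusion against plates the neighbours miR-23a and miR-27a were called in opposite directions, and their group with miR-24-1-5p averaged 0.09. miR-224 and miR-452 were both far lower in perfusion than on microcarriers, with miR-452 listed at 0 in all 4 perfusion libraries. The erythroid pair miR-451 and miR-144 averaged -5.01 on the log2 scale in perfusion against microcarriers, and miR-194a-5p with miR-192 averaged -3.22. miR-143-3p and miR-145-5p averaged 1.26, and miR-23b with miR-27b-3p and miR-24-2-5p averaged -1.19, though neither miR-23b nor miR-27b-3p was called.

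A hypothesis is that shared primary transcripts may set part of these changes. Gene order was taken from the Sscrofa11.1 RefSeq table, which placed 146 miRNAs, 50 of them in 20 groups of neighbours. The pooled SD of log2 fold changes within groups was 0.883 for perfusion against plate, 0.516 for microcarriers against plate and 0.596 for perfusion against microcarriers. Shuffled miRNAs gave 1.27, 0.901 and 1.42 (10000 shuffles, one-sided permutation p adjusted over 3 comparisons 0.0138, 3e-04 and 3e-04). The test does not separate transcription from a shared outside source, which also keeps neighbours together, as with miR-451 and miR-144.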
